A study of Mus musculus with 5 samples.

How the data were processed

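Total RNA from flash-frozen liver was extracted with Trizol, depleted of ribosomal RNA and made into stranded total RNA libraries, per the labels' protocols. The labels give 2 control (DMSO) libraries and 3 MS417 libraries of male ob/ob mice caged alone, and groups and replicate numbers were taken from the sample titles. The submitters' processing notes name BWA 0.7.3 and the genome build mm9. The counting tool, its strand setting and its treatment of reads shared between transcripts are not given in the sources used here, so genes that overlap another gene or have a near-identical copy are uncertain.

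The authors deposited 3 tables, each with 1 control and 1 MS417 library, that hold read counts per RefSeq transcript, not normalized. Each deposited table lists only transcripts with at least 100 reads in 1 of its 2 libraries, as the counts themselves show. The deposited tables also hold log2 values, which were the counts times 1 factor per table that scales the shallower library to the deeper one, and their log2 difference, coded as control minus MS417. Those log2 columns were checked against the counts and not used further. Control 1 stood in 2 tables, where 18565 rows were shared and 0 differed. The tables listed 19584 transcripts in all, 17967 of them in every table. A transcript left out of a table had fewer than 100 reads in both of its libraries, so only transcripts in every table were tested. Of 14361 gene symbols, 13119 had such a transcript. Where a symbol had several, the transcript with the highest mean count was used. Coordinates are those of the tables (mm9), given with the first base counted as 1.

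The counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust priors, TMM scaling, default low-count filter, which removed 0 genes). The biological coefficient of variation was 17.5%. Both groups shared 1 estimate of the spread, with no covariate. P-values were adjusted with the Benjamini-Hochberg method over all 13119 genes, with a threshold of 0.05. TMM factors were 0.934 and 0.933 for the controls and 1.04, 1.05 and 1.05 for the MS417 libraries. CPM values are TMM-scaled, and a fold change is 2 to the power of the fitted log2 fold change. The SE of a log2 fold change was derived from the test. It is the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The lowest count of a tested gene in any library was 7, and median counts per library lay between 699 and 1132, so counting error is small beside the spread between mice for most genes.

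Before the data were examined, 41 gene lists were fixed, of which 39 had at least 5 tested members. They were tested as sets with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Of the 39 lists, 14 passed with the preset correlation, 7 in each direction, 0 with an estimated correlation and 4 with fry's test of movement in 1 direction. Fry's test of change in either direction passed 34. The genes named were also fixed by rule: the 10 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 1 and groups that do not overlap; up to 4 members per list by smallest p among those past the threshold, or up to 2 where none passed; and the genes Brd2, Brd3, Brd4, Hexim1, Myc, Apoa1, Gck, Pklr, Fasn, Scd1, Srebf1, Mlxipl, Pck1, G6pc and Cyp7a1. Ccr2, Il1b, Cxcl9 and the other markers of BET inhibition were put together as a group of 13, of which 10 were tested, after the values had been seen.

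The pipeline was tested on simulated counts for the 13119 genes of the MS417 against control comparison. Of 100 genes changed 2-fold and 100 changed 4-fold, 78 and 98 were recovered, with 29 false calls among 205. With nothing changed, 2 genes and 0 lists were called. The simulated genes varied independently, so the simulation does not check the list calls where genes of a list move together. In the data the estimated correlation within a list reached 0.717, for oxidative phosphorylation. Pairs of libraries within a group differed by far more than sampling noise (chi-square over degrees of freedom from 106 to 354), so no 2 were copies of 1 library. That they came from separate mice rests on the labels alone. The alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library totals), other filters, DESeq2 and limma-voom, all transcript rows, small non-coding genes left out, each library left out, the replicate number or the deposited pair as a block, and other thresholds. Added after the data were seen were values for transcripts left out of a table, removal of the trend over transcript length, and leaving out the 20 most abundant genes. GO terms, as the deposited tables attach them, were tested with Fisher's exact test (1-sided, SciPy 1.17.1) among 12772 tested genes with terms, for terms of 10 to 500 genes. Figures were drawn with matplotlib 3.10.9.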

Results

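Ribosomal-RNA-depleted total RNA was sequenced from the livers of male ob/ob mice, which lack functional leptin, overeat and develop obesity, insulin resistance and fatty liver. The 5 libraries carried the labels of 2 vehicle (DMSO) mice, called control 1 and control 2 here, and 3 mice given MS417, an inhibitor of the acetyl-lysine-binding bromodomains of the BET proteins (Brd2, Brd3, Brd4 and Brdt). Per the labels, intraperitoneal injections began at 10 weeks of age with 2.5 mg/kg MS417 for 15 days, went on at 5 mg/kg for 2 weeks, and the livers were taken at 14 weeks. The mice were caged alone. Each control mouse received the mean ration that the MS417 mice, with free access to food, had eaten on the day before. Over the 13119 genes tested, with 1 transcript per gene symbol, the library totals were 73792894 and 60611144 reads for controls 1 and 2, and 61680391, 80235526 and 54683010 reads for MS417 1, 2 and 3. The 10 most abundant genes held 21.9% and 20.1% of the control reads and 19.4%, 25% and 20.2% of the MS417 reads.

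The comparison asked which liver transcripts differed between MS417 and vehicle in obese mice. All directions below follow the sample labels. Transcripts commonly used as markers of BET inhibition, put together after the values had been seen, ran mostly against those labels, as set out below. In the libraries labelled MS417, and at camera's preset correlation between genes, the lists for lipid droplets, fatty acid synthesis and cholesterol synthesis were called higher as sets. Those for amino acid and urea metabolism, histones and cytosolic ribosomal proteins were called lower. None of these 6 lists passed with an estimated correlation (camera adjusted p from 0.401 to 0.792). With fry only those for lipid droplets and cholesterol passed (adjusted p from 0.095 to 0.171 for the other 4), and 6 of the 34 ribosomal protein genes passed singly. The lipid droplet genes Cidea and Cidec rose 47.3-fold and 38.1-fold, and Scd1, the stearoyl-CoA desaturase, rose 12.6-fold (23.6-fold without control 1). Bhmt, which remethylates homocysteine, and Cth, which makes cysteine from cystathionine, fell 3.90-fold and 5.39-fold. Srebf1 and Mlxipl, which encode the lipogenic transcription factors SREBP1 and ChREBP, fell 2.57-fold and 1.86-fold. The call of Mlxipl was lost without control 1, control 2 or MS417 3.

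Of the 13119 genes, 1640 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1027 were higher and 613 were lower in the libraries labelled MS417, and 3995 genes had an unadjusted p under 0.05. Among the 1640, 581 were at least 2-fold higher and 205 at least 2-fold lower. The 3 MS417 libraries lay on the same side of both control libraries for 6418 genes, or 48.9%, where chance gives 20%. The first principal component held 66.4% of the variance and separated the groups, with the controls at -36.1 and -42.3 and the MS417 libraries between 19.1 and 34.3. The number of calls depended on the few libraries, with 420 genes past the threshold without control 1, 255 without control 2 and 920 without MS417 3. Of 133 genes named here that passed, 46 stayed past the threshold whichever library was left out. With scaling to library totals alone, the median log2 fold change of all genes moved from 0.039 to 0.20 and the share of higher calls from 62.6% to 83.2%, and with the trend over transcript length removed that share was 49.4%.

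The 10 largest increases were taken among genes past the threshold with an average log2 CPM of at least 1 and groups that did not overlap. They were in Cidea, Cidec, Serpina12, 2010003K11Rik, Niacr1, Aqp8, Pnpla3, Saa2, Sdcbp2 and Fgf21. Controls 1 and 2 had only 18 and 7 reads for Niacr1 and 32 and 30 for Sdcbp2. Cidea (NM_007702, mm9 chromosome 18, 67503218 to 67527448, plus strand) had 4.82 ± 1.6 CPM in the controls (SD, n = 2) and 228 ± 59 CPM in the MS417 libraries (SD, n = 3), a log2 fold change of 5.56 (SE 0.35, edgeR adjusted p = 0.00053). Cidec (NM_178373, mm9 chromosome 6, 113374630 to 113385749, minus strand) went from 3.80 ± 0.36 to 145 ± 20 CPM, a log2 fold change of 5.25 (SE 0.22, edgeR adjusted p = 9.5e-05). The log2 fold change was 4.38 for Serpina12, which encodes the adipokine vaspin, 4.31 for 2010003K11Rik, 4.02 for Niacr1, the niacin and hydroxybutyrate receptor, and 4.01 for Aqp8, a water and peroxide channel. It was 3.97 for Pnpla3, a lipid droplet protein, 3.96 for the acute phase gene Saa2, 3.72 for Sdcbp2 and 3.67 for the hormone Fgf21. Across these 10 genes the edgeR adjusted p lay between 9.5e-05 and 0.020. Without control 1 the log2 fold change of Niacr1 was 4.69 and that of Pnpla3 4.86, and without MS417 2 those of Pnpla3 and Saa2 were 3.10 and 3.32.

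The 10 largest decreases were in Sult2a1, Sult2a2, Sult2a5, Hist2h3c1, Hist2h3c2, Cyp26a1, Hist1h4i, Zfp791, Fmo3 and Sftpa1, with edgeR adjusted p between 0.0013 and 0.032. The steroid and bile acid sulfotransferase Sult2a1 (NM_001111296, mm9 chromosome 7, 14381595 to 14422759, minus strand) had 284 and 34.0 CPM in controls 1 and 2 and 0.109, 1.94 and 0.593 CPM in MS417 1, 2 and 3, and fell by 7.43 on the log2 scale (SE 1.13). Its relatives Sult2a2 and Sult2a5 had log2 fold changes of -4.99 and -4.69. The log2 fold change was -3.70 for Cyp26a1, which breaks down retinoic acid, -2.61 for the flavin monooxygenase Fmo3, -2.84 for the zinc finger gene Zfp791 and -2.54 for the surfactant protein gene Sftpa1. It was -4.31, -4.02 and -3.23 for the histone genes Hist2h3c1, Hist2h3c2 and Hist1h4i. Cyp26a1 had 616 and 194 CPM in controls 1 and 2. Without control 1 the log2 fold changes of Sult2a1, Sult2a2, Sult2a5, Cyp26a1, Zfp791 and Hist2h3c1 were -5.22, -4.02, -4.10, -2.64, -1.83 and -3.62, and without control 2 those of Sult2a1 and Cyp26a1 were -8.28 and -4.31. Without MS417 2 those of Sult2a1, Sult2a2 and Sult2a5 were -8.86, -6.75 and -5.39, and without MS417 3 those of Fmo3 and Hist2h3c2 were -3.24 and -4.62. Members of the Sult2a, Saa2 and histone families share sequence, so reads could be split between copies and their values are uncertain. Of the 20 genes, 13 stayed past the threshold whichever library was left out, and the other 7 lost the call without control 1 (Pnpla3, Saa2, Sult2a1, Sult2a2, Zfp791, Fmo3, Sftpa1). Most of these also lost it without control 2, and Sult2a1, Sult2a2 and Sftpa1 without MS417 3, with edgeR adjusted p of up to 0.255. With the replicate block Sult2a5 lost its call (edgeR adjusted p = 0.209), as did Pnpla3, Saa2, Sult2a1, Sult2a2, Zfp791 and Sftpa1.

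**Figure D1:**
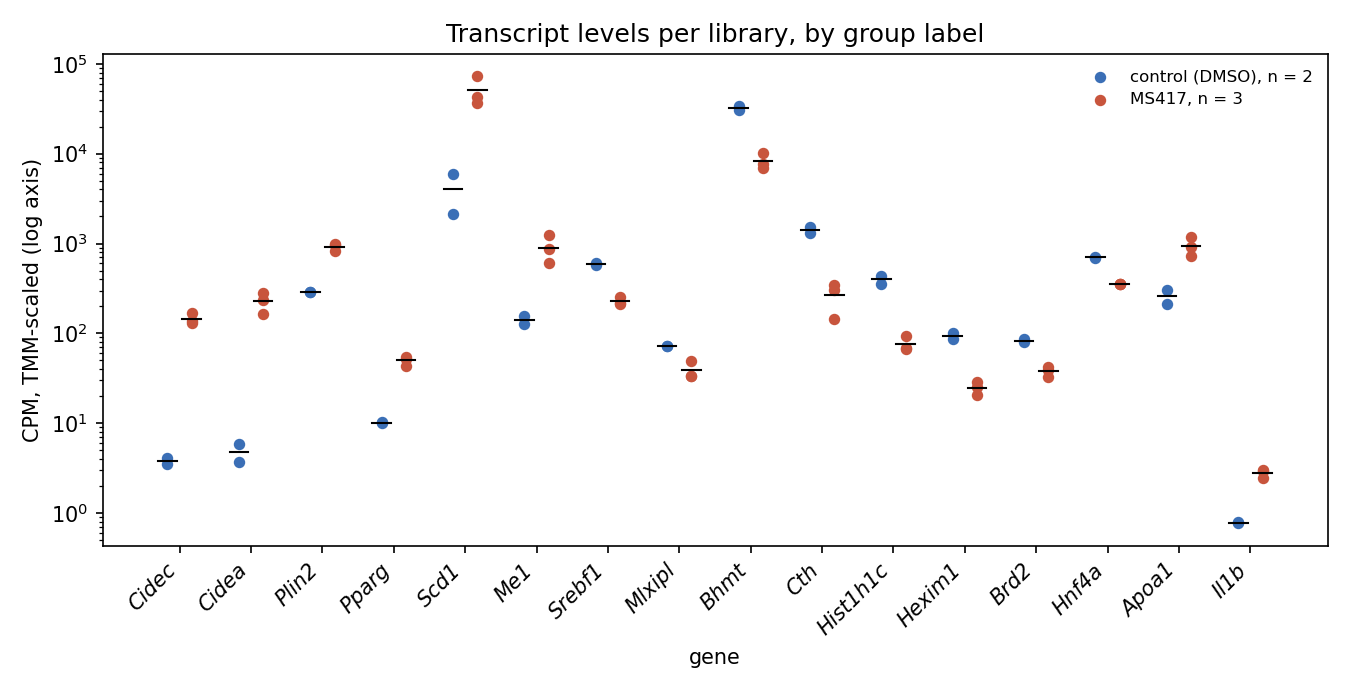
Transcript levels of 16 genes in each library, in TMM-scaled CPM on a log axis; points are libraries (2 control, 3 MS417, by label) and black lines are group means. The 3 MS417 libraries lie above both controls for Cidec, Cidea, Plin2, Pparg, Scd1, Me1, Apoa1 and Il1b and below both for the other 8 genes.

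Of the 20 lipid droplet and steatosis genes, 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 1.01 (camera adjusted p = 1.12e-06, with an estimated correlation 0.401, with fry 0.000962). Besides Cidea and Cidec, the adipogenic nuclear receptor Pparg rose by 2.31 (SE 0.17) and the droplet coat gene Plin2 by 1.67 (SE 0.17) on the log2 scale. Of the 30 genes of fatty acid and triglyceride synthesis, 17 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 1.07e-05, with an estimated correlation 0.657, with fry 0.095). Scd1 (NM_009127, mm9 chromosome 19, 44468940 to 44482199, minus strand) had 5935 and 2157 CPM in the controls and 36969, 72574 and 42844 CPM in the MS417 libraries, a log2 fold change of 3.65 (SE 0.52), or 4.56 without control 1. The NADPH-producing malic enzyme Me1 rose by 2.68 (SE 0.31), the desaturase Scd2 by 3.06 (SE 0.40) and the acetyl-CoA synthetase Acss2 by 1.58 (SE 0.20). The 2 members that fell were the regulators Srebf1, with a log2 fold change of -1.36 (SE 0.16), and Mlxipl, with -0.89 (SE 0.19). The calls of Scd2 and Acss2 were lost without control 2 (edgeR adjusted p = 0.0559 and 0.0573) and that of Mlxipl without control 1, control 2 or MS417 3 (up to 0.144). For Fasn, fatty acid synthase, the log2 fold change of 1.01 (SE 0.39) was not past the threshold (edgeR adjusted p = 0.12), and its groups overlapped. Fasn had 2248 and 1926 CPM in controls 1 and 2 and 2086, 5855 and 4675 CPM in MS417 1, 2 and 3. It passed in a fit with 1 MS417 library left out (edgeR adjusted p = 0.00722), though not without MS417 3.

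Cholesterol synthesis genes and SREBP2 targets rose in 13 of 25 cases and fell in 1 (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.87 (camera adjusted p = 1.07e-05, with an estimated correlation 0.657, with fry 0.0486). The mevalonate pathway kinase Pmvk rose by 1.33 (SE 0.15), and Sc5d and Cyp51, enzymes of the late sterol pathway, by 1.47 (SE 0.18) and 1.07 (SE 0.17). The member that fell was Insig1, which holds SREBP proteins in the endoplasmic reticulum, with a log2 fold change of -1.31 (SE 0.18). Without control 2 the calls of Insig1 and Cyp51 were lost (edgeR adjusted p = 0.0501 and 0.105).

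Amino acid and urea metabolism genes fell in 19 of 37 cases and rose in 0 (24 and 1 adjusted over the list alone), with a median log2 fold change of -0.76 (camera adjusted p = 7.89e-12, with an estimated correlation 0.657, with fry 0.095). Bhmt (NM_016668, mm9 chromosome 13, 94386846 to 94407713, minus strand), among the most abundant liver transcripts, went from 32087 ± 2135 CPM in the controls (SD, n = 2) to 8221 ± 1648 CPM in the MS417 libraries (SD, n = 3), a log2 fold change of -1.96 (SE 0.22). The log2 fold change was -2.43 (SE 0.33) for Cth, -1.16 (SE 0.16) for Asl, the urea cycle lyase, and -1.36 (SE 0.19) for the alanine aminotransferase gene Gpt. Without control 2 Asl and Gpt lost their calls (edgeR adjusted p = 0.0643 and 0.0605). Xenobiotic metabolism genes fell in 9 of 41 cases and rose in 6 (14 and 9 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0476, with an estimated correlation 0.792, with fry 0.171). The log2 fold change was -2.06 for the cytochrome P450 gene Cyp2c37, -1.24 for Ugt1a1, which conjugates bilirubin, -1.63 for the glutathione transferase gene Gsta2 and 1.34 for Cyp2c55. Cyp2c55 lost its call without control 2 (edgeR adjusted p = 0.0522). This list lost its call in 11 of 21 alternatives, among them the fits without control 2, MS417 1 or MS417 2 (camera adjusted p = 0.053, 0.0718 and 0.0717) and those with DESeq2 size factors or upper-quartile scaling (camera adjusted p = 0.0648 and 0.0509). It was lost also with the deposited pair as a block, unlisted transcripts at 0, the length trend removed or the 20 most abundant genes left out (camera adjusted p = 0.073, 0.0831, 0.115 and 0.0516). Cyp2c and Gst genes have close relatives between which reads could be split.

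Hepatocyte markers fell in 5 of 15 cases and rose in 1 (6 and 1 adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 0.0014, with an estimated correlation 0.657, with fry 0.115). The call of this list was lost without the 20 most abundant genes, some of them members (camera adjusted p = 0.192). The antitrypsin genes Serpina1a and Serpina1b, near-identical copies, had log2 fold changes of -1.43 and -1.20, and the liver transcription factor gene Hnf4a went from 699 ± 14 CPM in the controls (SD, n = 2) to 356 ± 0.93 CPM in the MS417 libraries (SD, n = 3), a log2 fold change of -0.97 (SE 0.14). The member that rose was Apoa1, the main protein of HDL, from 259 ± 68 to 939 ± 238 CPM, a log2 fold change of 1.86 (SE 0.27, edgeR adjusted p = 0.0058). Apoa1 lost its call without control 1 (edgeR adjusted p = 0.0539), and Serpina1a without control 2 (0.0522). Serpina1b and Hnf4a lost theirs without control 1 or control 2 (up to 0.0688 and 0.0724). Cytosolic ribosomal protein genes fell in 6 of 34 cases and rose in 0 (11 and 0 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 4.6e-07, with an estimated correlation 0.792, with fry 0.171). Rps6, Rps2, Rpl8 and Rps27 had log2 fold changes of -0.68, -0.73, -0.69 and -0.73, and such genes have many pseudogenes that could take or give reads. Rps2 lost its call whichever library was left out, and the other 3 lost theirs without any 1 library but MS417 1 (edgeR adjusted p of up to 0.315). Rps27 was lost in 11 of 20 alternatives, among them limma-voom, the stricter filter and the removal of the length trend. Of 40 oxidative phosphorylation genes 0 passed, also when adjusted over the list alone, while the list as a set was lower with a median of -0.26 (camera adjusted p = 0.000899, with an estimated correlation 0.809, with fry 0.381). Its members with the smallest p, Atp5h and Ndufb9, had log2 fold changes of -0.47 and -0.49 (edgeR adjusted p = 0.081 for both). With the trend over transcript length removed, the oxidative phosphorylation list was no longer called (camera adjusted p = 0.103).

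Of the transcripts of the drug's protein targets, only that of Brd2 passed. Brd2 (NM_001204973, mm9 chromosome 17, 34248964 to 34259552, minus strand) had a log2 fold change of -1.13 (SE 0.16, edgeR adjusted p = 0.0050), and Brd3, Brd4 and Brdt had log2 fold changes of -0.14 (SE 0.23), 0.12 (SE 0.23) and -0.43 (SE 0.16), not past the threshold (edgeR adjusted p = 0.72, 0.76 and 0.11). Hexim1, an inhibitor of the elongation factor P-TEFb, fell from 94.3 ± 9.6 CPM in the controls (SD, n = 2) to 24.9 ± 3.9 CPM in the MS417 libraries (SD, n = 3), a log2 fold change of -1.92 (SE 0.17, edgeR adjusted p = 0.0012). In the list of BET proteins and elongation factors these were the 2 of 14 members that passed (2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.186), its mean of -0.21 differing in sign from its median of 0.026. Replication-dependent histone genes fell in 11 of 21 cases and rose in 0 (14 and 0 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 6.2e-09, with an estimated correlation 0.657, with fry 0.095). Hist1h1c and Hist1h2bc, from which polyadenylated transcripts are also known, had log2 fold changes of -2.39 (SE 0.19) and -1.90 (SE 0.16). Hexim1, Brd2 and these histone genes are commonly reported to rise under BET inhibitors, and Ccr2, Il1b and Cxcl9 to fall. Markers of this kind were put together as a group after the values had been seen. In the libraries labelled MS417, of 10 such markers tested, 8 passed the threshold, 7 against the reported direction and 1, Apoa1, with it. Of these 7, Brd2 was not past the threshold without control 2 (edgeR adjusted p = 0.0556), Ccr2 without control 1 or control 2 (0.0538 and 0.0643), and Cxcl9 without control 2, MS417 2 or MS417 3 (up to 0.124). Myc, another gene reported to fall, was not listed in every table and was not tested, with 25 reads in control 1 and 111 and 143 in MS417 1 and 2. The cytokine gene Tnf, also not tested, ran the other way, with 124 reads in control 1 and 59 and 104 in MS417 1 and 2.

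Of 26 NF-kB targets and inflammatory cytokines in the list, only 15 were listed in every table and tested. Of these 15, 8 rose and 0 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 0.000264, with an estimated correlation 0.657, with fry 0.0486). Among members not tested, Tnf had 124 reads in control 1 and 59 and 104 in MS417 1 and 2. Ccl2 had 45 reads in control 1 and 185 and 118 in MS417 1 and 2. The cytokine gene Il1b rose by 1.85 (SE 0.21) to 2.82 ± 0.30 CPM (SD, n = 3), the chemokine gene Cxcl1 by 2.11 (SE 0.33) and the adhesion molecule gene Vcam1 by 0.65 (SE 0.15), and the chemokine gene Cxcl9 rose 2.82-fold. The call of Vcam1 was lost without control 1, control 2 or MS417 3 (edgeR adjusted p of up to 0.177) and that of Cxcl9 without control 2, MS417 2 or MS417 3 (up to 0.124). Without control 1 the log2 fold changes of Cxcl1 and Cxcl9 were 2.78 and 2.26. Of 8 genes of MHC class II and antigen presentation 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 0.0224, with an estimated correlation 0.657, with fry 0.0684). H2-Eb1, H2-Aa and H2-Ab1 rose by 1.62, 1.40 and 1.16, and Ciita, the transactivator of these genes, had a log2 fold change of -1.57 (SE 0.19). The call of this list was lost without control 2 or MS417 1, with library totals and with all transcript rows (camera adjusted p = 0.0601, 0.0648, 0.0664 and 0.295). That of H2-Ab1 was lost without control 1 or control 2 (edgeR adjusted p of up to 0.0789). Cell cycle genes rose in 4 of 21 cases and fell in 0 (9 and 0 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 0.0014, with an estimated correlation 0.792, with fry 0.283). Ccnd1, Mcm2, Rrm2 and Mcm3 rose by 1.80, 1.60, 1.48 and 1.20. Without control 2 all 4 lost their calls, Mcm2 also with the replicate block, Rrm2 in 7 and Mcm3 in 8 of 20 alternatives. Both Rrm2 and Mcm3 were lost without any 1 library but MS417 1 (edgeR adjusted p of up to 0.289).

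Male-biased liver genes rose in 6 of 20 cases and fell in 1 (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.76 (camera adjusted p = 0.0496, with an estimated correlation 0.809, with fry 0.296). Cyp2u1, Elovl3 and Nudt7 rose by 2.72, 3.63 and 1.81, and Moxd1 had a log2 fold change of -1.45. The call of the list was lost without control 1, MS417 1 or MS417 3 (camera adjusted p = 0.25, 0.287 and 0.0568), with library totals (0.192) and with unlisted transcripts at 0 (0.0823). The female-biased list did not pass (camera adjusted p = 0.717), with Cyp17a1 and Tox higher by 3.54 and 1.91 and Sult2a1 and Sult2a7 lower, the latter with a log2 fold change of -1.94. Elovl3 and Nudt7 lost their calls without control 1 or control 2, Moxd1 and Sult2a7 without control 2, Tox without control 1, and Sult2a1 without control 1 or MS417 3. With the replicate block Cyp17a1, Sult2a1, Elovl3 and Sult2a7 lost their calls.

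**Figure D2:**
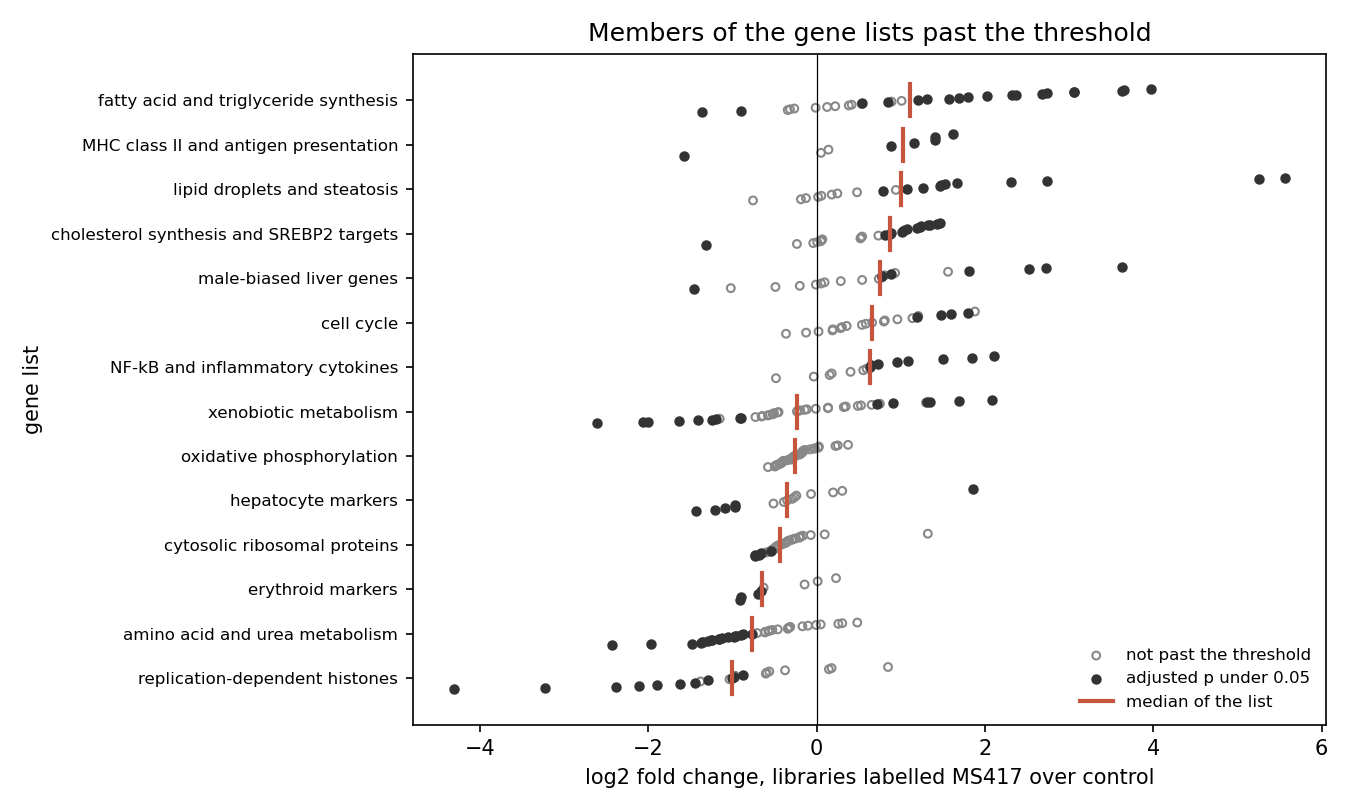
Log2 fold change of each tested member of the 14 gene lists that passed the set test, libraries labelled MS417 over control; filled points had an adjusted p under 0.05 and red bars are list medians. Medians run from -1.01 for replication-dependent histones to 1.11 for fatty acid and triglyceride synthesis, and scaling to library totals turned the sign of none of these 14 medians.

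Genes of glucose use changed singly, and their lists did not pass. In the glycolysis list (camera adjusted p = 0.306) 5 of 20 members rose and 1 fell (5 and 2 adjusted over the list alone). Gck, the liver glucokinase, rose by 1.82 (SE 0.18, edgeR adjusted p = 0.0015), the pyruvate kinase gene Pklr by 1.29 (SE 0.18, edgeR adjusted p = 0.0054) and Aldoa by 0.81, while Pfkl had a log2 fold change of -0.68. Without control 2 the edgeR adjusted p of Pklr was 0.0772. In the gluconeogenesis and glycogen list (camera adjusted p = 0.773) 2 of 18 members rose and 2 fell (4 and 4 adjusted over the list alone). The glycogen-targeting subunit genes Ppp1r3g and Ppp1r3c had log2 fold changes of 3.02 and -1.95, Gys2, the liver glycogen synthase, had 0.81, and Slc37a4, the glucose-6-phosphate transporter, had -1.06. Pck1 and G6pc, which encode the key gluconeogenic enzymes, had log2 fold changes of -0.35 (SE 0.36) and -0.19 (SE 0.26), not past the threshold (edgeR adjusted p = 0.55 and 0.65). In the list of fatty acid oxidation and PPARalpha targets (camera adjusted p = 0.773) 4 of 30 members rose and 4 fell (4 and 4 adjusted over the list alone), among them Pex11a and Vnn1 at 1.55 and 2.00 and Cyp4a14 at -1.34. In the bile acid list (camera adjusted p = 0.503) 2 of 23 rose and 1 fell (2 and 2 adjusted over the list alone). The sterol 12-alpha-hydroxylase gene Cyp8b1 rose by 2.40 (SE 0.25), Cyp39a1 rose by 0.86, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.84 (SE 0.16, edgeR adjusted p = 0.015), a call lost without control 1 or control 2 (up to 0.145). Likewise Aldoa and Pfkl lost their calls without control 1 or control 2, Slc37a4 and Vnn1 without control 2, Cyp4a14 without control 1, and Gys2 and Cyp39a1 without control 1, control 2 or MS417 3 (edgeR adjusted p of up to 0.207).

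Secreted liver proteins also changed in both directions. Of 21 genes of apolipoproteins and lipoprotein secretion (camera adjusted p = 0.657) 4 rose and 1 fell (7 and 3 adjusted over the list alone), with Apoa4, Pltp and Mttp at 3.28, 2.34 and 1.15. In the acute phase list (camera adjusted p = 0.503) 7 of 29 rose and 1 fell (8 and 3 adjusted over the list alone), with Saa1 and Orm1 at 3.59 and 1.01. In the complement and coagulation list (camera adjusted p = 0.139) 3 of 38 rose and 5 fell (4 and 5 adjusted over the list alone), with C4b and C4a, near-identical copies, at 1.19 and 1.02, F7 at -1.10, and Kng1, a kininogen gene, falling from 3911 ± 358 CPM in the controls (SD, n = 2) to 1951 ± 226 CPM (SD, n = 3). Without MS417 1 this list passed (camera adjusted p = 0.0249). Among liver transcription factors (camera adjusted p = 0.379) 4 of 19 rose and 1 fell (4 and 1 adjusted over the list alone), with Hnf1a, Foxa1 and Zhx2 at 1.51, 1.25 and 1.58. Each of these 3 lost its call without control 1 or control 2 (edgeR adjusted p of up to 0.209), as did Hnf4a, the member that fell. Zhx2 lost it in 7 of 20 alternatives, among them limma-voom and the deposited pair as a block. In the insulin and growth hormone list (camera adjusted p = 0.173) 2 of 20 rose and 0 fell (1 and 0 adjusted over the list alone), namely Igfbp1 by 3.10 (SE 0.32) and Igf1 by 0.75 (SE 0.20). Without control 2 this list passed (camera adjusted p = 0.0281). Igf1 lost its call without any 1 library but MS417 2 (edgeR adjusted p of up to 0.25). In this paragraph Mttp, Orm1, Kng1 and C4a lost theirs without control 1 or control 2, Saa1 and F7 without control 2 and C4b without control 1 (up to 0.153).

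Stress and signalling lists did not pass either with all 5 libraries. Of 24 interferon response genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.173), with Oasl1 and Gbp3 at 1.40 and 1.15 and Stat2 at -0.75. Oasl1 was at 2.02 without control 1. This list passed without control 1 (camera adjusted p = 0.000714) and was at 0.965 without control 2. Of 15 p53 targets 4 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.234), with Btg2, Gdf15 and Fas at 1.84, 1.60 and 0.77 and Plk2 at -0.61. Of 26 unfolded protein and integrated stress genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.599), with Chac1 at 1.75 and Herpud1 and Atf4 at -1.45 and -0.76. Of 18 immediate-early and heat shock genes 2 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.773), with Klf6 at 1.02 and Ier5 and Dnajb1 at -0.88 and -0.68. Of 19 glucocorticoid targets 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.717), with Lcn2 at 2.33 and Tsc22d3 at -1.72. Of 21 circadian genes 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.773), the latter Tef at -0.64. Of 25 matrix and fibrosis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.747), with Thbs1, Serpine1 and Lamb3 at 0.96, 1.43 and 1.33 and Col1a2 at -0.70. Of the genes named in this paragraph, only Btg2 and Herpud1 stayed past the threshold whichever library was left out, and Plk2, Tef, Dnajb1 and Lcn2 were lost in 4 of these 5 fits (edgeR adjusted p of up to 0.254). The direction that camera gave and the sign of the median differed in 8 of the 39 lists tested, namely the BET, bile acid, apolipoprotein, stress response, female-biased, glucocorticoid, stellate and adipocyte lists, none of them among the 14 that passed. The mean and the median differed in sign in 8 lists, the BET, apolipoprotein, stress response, female-biased and adipocyte lists and those of gluconeogenesis, fatty acid oxidation and Kupffer cells.

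Erythroid markers fell in 4 of 8 cases and rose in 0 (4 and 0 adjusted over the list alone), with a median log2 fold change of -0.65 (camera adjusted p = 0.0141, with an estimated correlation 0.657, with fry 0.106), among them Snca, Hbb-b1, Hba-a2 and Hba-a1 at -0.91, -0.90, -0.69 and -0.66. The call of the list was lost without control 1 and with the length trend removed (camera adjusted p = 0.0814 and 0.0753), and reads of the near-identical globin genes could be split between copies. In the Kupffer cell and macrophage list (camera adjusted p = 0.462) 2 of 23 rose and 2 fell (2 and 2 adjusted over the list alone), with the monocyte chemokine receptor Ccr2 and the receptor Cd14 at 3.40 (SE 0.48) and 1.12 and the resident macrophage genes Vsig4 and Timd4 at -0.71 and -0.52. Controls 1 and 2 had only 29 and 23 reads for Ccr2 and 71 and 53 for Cd14. Of 15 endothelial markers 0 passed, with a median of 0.24 (camera adjusted p = 0.26) and Lyve1 and Pecam1 at 0.69 and 0.48. Of 14 stellate cell markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.857), namely Tagln at 0.63 and Gfap at -1.01. Of 8 adipocyte markers 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.173), namely Cidec, Aqp7 at 1.81 and Lipe at 1.14. Without control 2 this list passed (camera adjusted p = 0.0281). Of 5 pancreatic acinar markers 0 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.306), with Cpb1 at -0.80. Of 7 cholangiocyte and 5 neutrophil markers 0 passed (camera adjusted p = 0.957 and 0.462), with Slc5a1, Krt19, Mpo and Csf3r at 0.63, -0.47, -0.53 and 0.29. Too few lymphocyte markers (3) and muscle and mesothelial markers (4) were measured for a test, with medians of -0.46 and -0.14. Cd79a and Cd3g had log2 fold changes of -0.52 and -0.46, not past the threshold, and Myh4, which passed, had -0.65. Tagln, Timd4 and Myh4 lost their calls whichever library was left out (edgeR adjusted p of up to 0.311). Tagln was lost also with DESeq2 size factors and both blocks. Hba-a1 and Cpb1 lost theirs in 4 of these 5 fits, Snca, Hbb-b1, Hba-a2 and Cd14 in 3, Ccr2, Vsig4 and Gfap without control 1 or control 2, and Lipe without control 1 (edgeR adjusted p of up to 0.273).

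The deposited tables set the libraries side by side in 3 pairs, control 1 with MS417 1, control 1 with MS417 2, and control 2 with MS417 3. The sign of the log2 fold change was the same in all 3 pairs for 63.2% of the 13119 genes, against 33.4% for simulated unchanged groups with the same shared control. For the 2 combinations of pairs with no shared library the share was 77.3% and 75.2%, against 50.2% and 50.0% in the simulation. For the combination that shared control 1 it was 73.9%, against 66.5%. The simulated genes varied independently, so how far these shares stray in unchanged mice whose genes move together is not known. All 1640 genes past the threshold had the same sign in all 3 pairs, a share partly set by the selection of these genes on the same libraries.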

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

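Of the alternatives here, the values set for unlisted transcripts, the removal of the length trend and the omission of the 20 most abundant genes were chosen after the results were seen, and all others before. None of the 1640 calls was called in the opposite direction under any alternative. With upper-quartile scaling, DESeq2 size factors or limma-voom, 1624, 1584 and 1575 of them were called again. Counts outside 1.5 times the reported 1640, 1027 higher and 613 lower were as follows, and the cause was not tested unless given. Library totals gave 1895 higher and 382 lower, since every log2 fold change shifts up by the same amount. DESeq2 called 2615 genes, 1151 of them lower. Leaving out 1 library, which leaves fewer samples and at times a lone control, gave 255 to 1899 genes, 174 to 1143 higher and 81 to 756 lower. Setting unlisted transcripts to 0 gave 1060 genes, 662 higher and 398 lower, and removing the length trend 974 lower. Thresholds of 0.1 and 0.01 gave 2854 and 400 genes.

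Of the 14 lists, 0 passed with an estimated correlation, 3 with fry, and 10 of the 14 passed whichever library was left out. Without the length trend 3 were lost, oxidative phosphorylation, erythroid markers and xenobiotic metabolism, with adjusted p of 0.103, 0.0753 and 0.115. The median of the oxidative phosphorylation list went from -0.26 to -0.22 (SD over members 0.21), that of erythroid markers from -0.65 to -0.46 (SD 0.43) and that of xenobiotic metabolism from -0.23 to -0.30 (SD 1.03), while the median of all genes went from 0.039 to -0.047. Hepatocyte markers and xenobiotic metabolism were lost without the 20 most abundant genes (0.192 and 0.0516), some of which are list members. Unlisted transcripts at 0 also lost xenobiotic metabolism and male-biased genes (0.0831 and 0.0823), library totals male-biased genes and MHC class II (0.192 and 0.0664), and all transcript rows MHC class II (0.295). Lists gained were glycolysis, the insulin axis, BET proteins and complement with all transcript rows (0.0268, 0.00887, 0.0306 and 0.0377), adipocyte markers with fry (0.0486) and the interferon list with the replicate block (0.046).

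Of 133 named genes past the threshold, 46 stayed past it whichever library was left out. Without control 1 and control 2, 66 and 78 were lost, and without MS417 1, 2 and 3, 7, 16 and 32. No named gene past the threshold turned direction. Of those not past it, the log2 fold change turned to 0.028 for Brd3 with library totals and to -0.060 for Brd4 without the length trend. With 1 library left out it ran from -0.088 (without MS417 2) to 0.23 for Brd4, and from -0.75 to 0.21 for Pck1 and -0.49 to 0.18 for G6pc, positive without control 2. Of the lists, 8 turned direction in some fit, none of them past the threshold there or in the reported fit. With library totals it was the circadian list (adjusted p = 0.966). With all transcript rows it was gluconeogenesis and the circadian list (0.907 and 0.859). With the deposited pair as a block it was the glucocorticoid and cholangiocyte lists (0.996 and 0.909), and with unlisted transcripts at 99 the cholangiocyte list (0.996). Without the length trend it was the matrix list (0.995), and with fry fatty acid oxidation, female-biased and stellate lists (0.685, 0.979 and 0.979). These 8 also turned with 1 library left out, with adjusted p from 0.262 to 0.945 for the circadian list, 0.598 to 0.965 for gluconeogenesis, 0.637 to 0.965 for fatty acid oxidation, 0.272 to 0.958 for female-biased, 0.439 to 0.982 for matrix, 0.159 to 0.776 for glucocorticoid, 0.598 to 0.958 for stellate and 0.587 to 0.951 for cholangiocyte genes.

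Whether the replicate numbers 1 and 2 paired the samples cannot be told from 2 controls, whose deviations from their mean are mirror images. The deviations of control 1 and MS417 1 from their group means correlated at 0.201 over genes and those of control 2 and MS417 2 at -0.0992. With the replicate number as a block, on the 4 libraries that share one, 1251 genes passed, 823 higher and 428 lower, 33 named calls were lost, 15 lists passed, and the stellate list turned direction (adjusted p = 0.912). Over the deposited pairs these correlations were 0.201, 0.0992 and 0.366, and 2 pairs share control 1. With this block 1447 genes passed, and 13 named calls and xenobiotic metabolism (0.073) were lost. Tests on RPKM or on pseudocounts were not run, since counts were used. Transcripts under 100 reads in both libraries of a table, such as Myc, were left out of it, so no count was available there for the test.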

Other observations

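Terms of the Gene Ontology were tested, and the genes named in this paragraph and the next were chosen, after the results were seen. Of 1889 terms tested in both directions, 18 were enriched among the higher and 13 among the lower genes (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). This test treats genes as independent, so its p-values here and in the next paragraph make no allowance for genes that move together. They do not measure the spread between mice. Immune response genes were higher in 19 of 77 cases (odds ratio 3.91, adjusted p = 0.00209) and inflammatory response genes in 23 of 108 (odds ratio 3.24, adjusted p = 0.00279). The chemokine receptor gene Ccr5 and the MHC class I gene H2-Q7, which has close copies, had log2 fold changes of 3.21 (SE 0.27) and 1.96 (SE 0.21), and the Toll-like receptor genes Tlr5 and Tlr13 had 2.19 (SE 0.24) and 1.58 (SE 0.20). Among lipid metabolism genes 51 of 330 were higher (odds ratio 2.21, adjusted p = 0.00112), among them Fabp5 at 3.50 (SE 0.25), the monoacylglycerol acyltransferase gene Mogat1 at 1.52, the fatty acid elongase gene Elovl2 at 1.38 and Insig2, the relative of Insig1, at 1.12.

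Monooxygenase genes were lower in 22 of 94 cases (odds ratio 6.67, adjusted p = 4.86e-07), with the cytochrome P450 genes Cyp3a13 and Cyp2c29 at -1.41 and -1.19. Glutathione binding genes were lower in 5 of 10 cases (odds ratio 21.3, adjusted p = 0.00911), among them Gsta4 and Lancl1 at -1.01 and -0.69. Genes of erythrocyte development were lower in 6 of 17 cases (odds ratio 11.6, adjusted p = 0.014), led by the erythroid transcription factor gene Klf1 at -1.79 (SE 0.23), and nucleosome genes in 7 of 21 (odds ratio 10.7, adjusted p = 0.00719), with the linker histone gene H1f0 at -1.27 (SE 0.14). Peptidase inhibitor genes were lower in 10 of 59 cases (odds ratio 4.37, adjusted p = 0.0375), among them Mug1 and Spink11 at -0.94 and -1.18. Genes that promote fatty acid synthesis were lower in 5 of 10 cases (odds ratio 21.3, adjusted p = 0.00911), namely Srebf1, Mlxipl, Hnf4a, Mid1ip1 and Agt, the last 2 at -1.94 and -1.04. Of these 18 added genes, 10 stayed past the threshold whichever library was left out, and 7 were lost without control 1 and 7 without control 2.

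All tests in the paragraphs that follow were chosen after the results were seen. Of the 10 splits of the 5 libraries into 2 and 3, 1 (the labelled one) gave 1640 genes, and the highest of the other splits gave 0 genes with edgeR. Every other split put control and MS417 libraries into the same group, which widens the spread within that group. Few calls are thus to be foreseen there, whatever separated the labelled groups. With 10 splits no share under 0.05 can be reached.

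Known markers of BET inhibition mostly ran against their reported direction. Of 8 markers past the threshold, 7 did so (Hexim1, Brd2, Hist1h1c and Hist1h2bc lower, Ccr2, Il1b and Cxcl9 higher) and Apoa1 did not. The markers were put together after the values had been seen, so this share is no independent test of the labels. Of those fixed by gene name beforehand and tested, Hexim1 and Brd2 ran against the reported direction and Apoa1 with it. A trend over transcript length is not the cause, since all 13 of Hexim1, Brd2 and the called histone genes stayed lower and past the threshold once it was removed. An exchange of the group labels over all 5 libraries may account for the 7 markers, and such an exchange would turn every direction in the report. A biological difference between the groups, such as an adaptation after weeks of injections or a rebound after the last dose, was not tested and stays open, as the time from the last injection to tissue collection is not given in the labels.

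Of 30 lipid synthesis and 20 droplet genes, 17 and 11 were higher, while Srebf1 and Mlxipl were lower. A later last meal in the MS417 mice could raise such genes. It cannot be told apart from the drug by design, since the MS417 mice ate freely while the controls received a ration. Fasting-induced genes went both ways. Over 20 such genes the median log2 fold change was 0.143 (SD over genes 1.26), with 4 higher, among them Fgf21 and Igfbp1, and 2 lower, Cyp4a10 and Cyp4a14. That leaves a drug effect, feeding and exchanged labels open.

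Of 37 amino acid, 21 histone and 34 ribosomal protein genes, 19, 11 and 6 were lower and 0 higher. A trend over transcript length, with a Spearman correlation over genes of 0.178 between length and log2 fold change, is not the whole cause, since the lists stayed lower once it was removed (camera adjusted p = 1.28e-10, 2.93e-06 and 0.000888 at the preset correlation, a call that none held with an estimated one, at adjusted p = 0.657, 0.657 and 0.792 before removal) and 19 of 19 called amino acid genes stayed past the threshold. A smaller share of hepatocytes would raise the markers of all other cells alike, if those cells kept their own proportions. The markers of 15 endothelial and 8 erythroid genes moved apart instead, with median log2 fold changes of 0.24 and -0.65 (exact 2-sided permutation test of the means over genes, p = 0.000241). The medians of the Kupffer cell, stellate, cholangiocyte and neutrophil lists lay between, at -0.17, 0.062, 0.12 and -0.16. This test cannot exclude a smaller share of hepatocytes, since it treated genes that can move together as independent. A change in the erythroid cells themselves also stays open. A smaller share of hepatocytes, the drug, feeding and exchanged labels remain possible explanations and were not told apart by these tests.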
